A study of Drosophila melanogaster with 2 samples.

How the data were processed

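Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 24 hours, of both sexes, from a transgenic line with eGFP fused to the C terminus of CG4854 (CG4854-eGFP). Per the labels, the fusion protein was recovered with an antibody against GFP, chromatin was sheared by sonication, and libraries were read on Illumina HiSeq instruments. The 2 samples, biological replicates 3 and 2, form 1 group, so no comparison between conditions was possible.

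The authors deposited peak lists in narrowPeak format on both the dm3 and the dm6 genome builds. For each replicate there was a list of 30000 candidate peaks, derived from that replicate's own alignments and a control file shared by both replicates, per the text that accompanies the deposit. A further list of 30000 candidates came from the pooled alignments. A final set of peaks had passed a threshold on the irreproducible discovery rate (IDR), a measure of how well ranks repeat between replicates, and was derived from these 3 lists. The aligner, the peak caller, the IDR threshold and the number of reads per sample are not given in the sources used here. The signal of each peak is the authors' score, in the peak caller's own scale, and it was used only to rank and describe peaks within a list. The deposited q-value column holds −log10 values per the narrowPeak format. In the IDR set it holds 1 constant value per build, so signal alone was used for ranking. All 3106 dm6 IDR peaks were the 3106 highest-signal entries of the pooled list, and the same held for the 3716 on dm3. The summit offset deposited with each peak gave summit positions. Mock immunoprecipitations, untagged embryos and expression data were not analysed here.

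Coordinates are on dm6 (Release 6), counted from 1, and no coordinates were converted between builds. Genes and transcription start sites (TSSs) of protein-coding transcripts came from Ensembl release 115 (BDGP6 version 54), on arms 2L, 2R, 3L, 3R, 4 and X. Summits within 500 bp of a TSS were called promoter summits. Other summits were placed in the 5' UTR, coding exon, 3' UTR, intron or intergenic class, the first that held in that order. Background candidates were the 13096 pooled candidates that overlapped no IDR peak and ranked below the median signal of such candidates. The replicate lists were compared at their 3106 highest-signal entries, with summits within 100 bp counted as shared, against 1000 random relocations within arms. Positions relative to genes were compared with the same number of relocations (two-sided) and with background candidates by Fisher's exact test (two-sided). Counts per arm were compared with each arm's share of the total length by an exact two-sided binomial test. For 21 gene lists, members with a promoter peak were compared with all other protein-coding genes by Fisher's exact test (two-sided). Symbols were matched through current and older names, and 5 names had no match. Sequence was searched within 50 bp of each summit, on both strands, for 16 preset motifs (Fisher's exact test, two-sided, against background candidates). An exact McNemar test compared each summit with 1 window 500 bp away, on alternating sides by rank. All 32896 8-mers, merged with their reverse complements, were tested with odd-ranked peaks (one-sided Fisher's exact test), and those that passed were tested again with even-ranked peaks. Trends over 5 classes of peak signal were tested with 100000 permutations. All families of p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold.

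The tests of the report, the gene lists, the motifs and the rule for named genes were chosen before the data were examined; tests chosen later are named as such. The rule took the 25 strongest dm6 IDR peaks, each named by the nearest protein-coding TSS, CG4854 with any IDR peak within 5 kb, up to 4 members per list by signal, and the 10 8-mers with the smallest p in the odd-ranked peaks. Shares have exact Clopper-Pearson 95% intervals. Odds ratios have Woolf 95% intervals, with 0.5 added to each cell where a count was 0. A count of 0 is given with the share that 3 counts would make. Intervals cover counting error over peaks or genes only, since read depth is unknown. Peaks and genes are not biological replicates. Genes that lie in clusters or share a promoter are not independent of each other.

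The procedures were tested on simulated data. With promoter peaks at 40% of a list of 60 genes against 15% of the other genes, the list test recovered 96% of raised lists and called 0.5% of unchanged lists. The 8-mer search recovered 100% of 10 sequences, each planted in 3% of the windows. Lower shares and lists of other sizes were not simulated, so recovery there is unknown. Alternatives covered the distance that counts as shared, the number of top peaks, the TSS window, the background, the sequence window and a stricter peak set of the 1553 strongest. Each replicate was also left out in turn, with the 3106 highest candidates of the other replicate in place of the IDR set. Background windows matched 1 to 1 on GC (classes of 2.5 percentage points) and on promoter position served as an alternative. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.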

Results

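CG4854 encodes a zinc finger protein with a ZAD domain, a family of insect proteins that bind DNA. The samples were 2 biological replicates, numbered 3 and 2, of whole embryos aged 0 to 24 hours that carried a CG4854-eGFP fusion. The deposited IDR set on dm6 held 3106 peaks with a median width of 358 bp, and their signal ran from 95.2 to 1775.6 with a median of 146. Each replicate and the pooled data had a list of 30000 candidates. The number of reads behind these lists is unknown here.

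The first question was where the strongest CG4854-eGFP peaks lay and whether both replicates held them. The strongest peak lay at 3L, 19590409 to 19590841, with its summit 96 bp from the TSS of CG14100, a signal of 1775.6 in the pooled list and 988.3 and 784.5 in replicates 2 and 3. The next lay on X, 2703673 to 2704102, 22 bp from the TSS of Ugalt, a UDP-galactose transporter (signal 1736.1). The third, on 2L from 6612462 to 6612932, lay in an intron of CG11050, 1040 bp from its TSS (1649.0). The fourth lay in an intron of ush on 2L, 480854 to 481308, 1403 bp from the TSS of cbt, which was the nearest (1514.9). Of the 25 strongest peaks, 17 lay within 500 bp of a TSS, 5 in introns and 3 between genes, and all 25 ranked 100th or better in both replicates. They were picked by pooled signal from a set chosen for agreement between replicates, which favours high ranks in both.

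Among the other peaks of these 25, promoter summits lay at px (1291.5), the Polycomb group gene ph-p (1273.3) and Chro, which encodes the chromatin protein Chromator (1237.6). Further promoter summits lay at PNPase (1216.6), Art3 (1116.2), Tcs5 (1073.2), CG1888 (993.4), CenG1A (981.3), CG9147 (974.7) and mRpL41 (938.4). The remaining ones lay at CG18549 (919.9), Tm1, which encodes a tropomyosin (874.3), Usp15-31 (872.9), CG7601 (851.7) and larp (849.4). Intron summits lay in Lk6 (1097.6), CG32772 (971.2) and CG9663 (922.8). The 3 intergenic summits had CG4004 (1082.9), DNAlig3 (888.8) and hll (852.5) as the gene with the nearest TSS, at 5096, 1303 and 2929 bp.

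CG4854 itself (FBgn0038766; 3R, 20028058 to 20029561, plus strand) had no IDR peak at its own promoter. The pooled list held a candidate there, with its summit at 20028231, 173 bp inside the gene, and a signal of 43.9, which ranked 9771. An IDR peak at 20031637 to 20031812 had its summit 2098 bp past the end of CG4854 and 164 bp from the TSS of idc (signal 195.3, rank 913). No other IDR peak lay within 5 kb of the gene.

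The replicates shared most of their strongest peaks. Of the 3106 highest candidates of replicate 2, 1978 (63.7%, 95% interval 62.0 to 65.4) had a summit within 100 bp of one of the 3106 highest of replicate 3. Random relocation gave a median of 0.483% and at most 0.901% (one-sided permutation p over relocated positions = 0.001, the smallest that 1000 relocations can give). Both replicates had a candidate within 100 bp at 2936 of the 3106 IDR summits. Across these peaks the signals had a Spearman rho of 0.595 and a Pearson r of 0.696 on the log2 scale, as a description, since peaks are not replicates. The median log2 ratio of replicate 3 to replicate 2 was -0.07, the median absolute log2 ratio 0.36 and the SD 0.62. The IDR set was itself chosen for ranks that repeat between replicates, which favours matches at its summits. The candidate lists of both replicates rest on 1 shared control file.

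**Figure D1:**
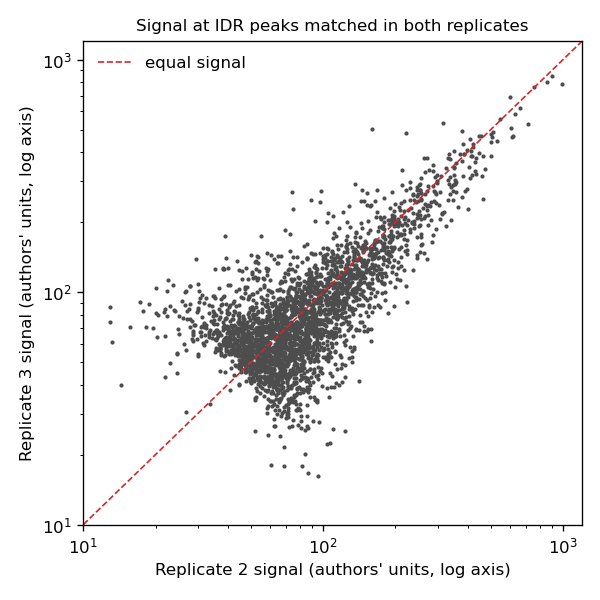
Signal of replicate 3 (y axis, log scale, authors' units) against replicate 2 (x axis, log scale, authors' units) at the 2936 IDR peaks with a candidate summit within 100 bp in both. Each point is 1 peak and the dashed line marks equal signal; Spearman's rho was 0.595.

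The next comparison asked which parts of genes held the peaks. Promoters held 1687 of the 3106 IDR summits (54.3%, 95% interval 52.5 to 56.1), against 17.6% of 13096 background candidates (odds ratio 5.57, 95% interval 5.12 to 6.05). The median of random relocations was 11.5%, so promoters were 4.71-fold over random positions (two-sided permutation p over relocated positions = 0.002, the smallest that 1000 relocations can give). The p of Fisher's exact test for promoters was too small to be represented. Coding exons held 6 summits (0.193%), against 8.04% of background candidates (odds ratio 0.0221, Fisher's exact test, two-sided, adjusted exact p = 8.76e-90) and 13.9% of random positions. The 3' UTRs held 20 summits (0.644% against 7.51%, adjusted exact p = 1.16e-66). Introns held 965 summits (31.1% against 45.2%, adjusted exact p = 1.22e-47) and intergenic DNA 406 (13.1% against 20.3%, adjusted exact p = 2.19e-21). The 5' UTRs outside promoter windows held 22 (0.708% against 1.36%, adjusted exact p = 0.00270), and against random positions no difference was detected (two-sided permutation p over relocated positions = 0.663). The 6 classes were adjusted together.

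**Figure D2:**
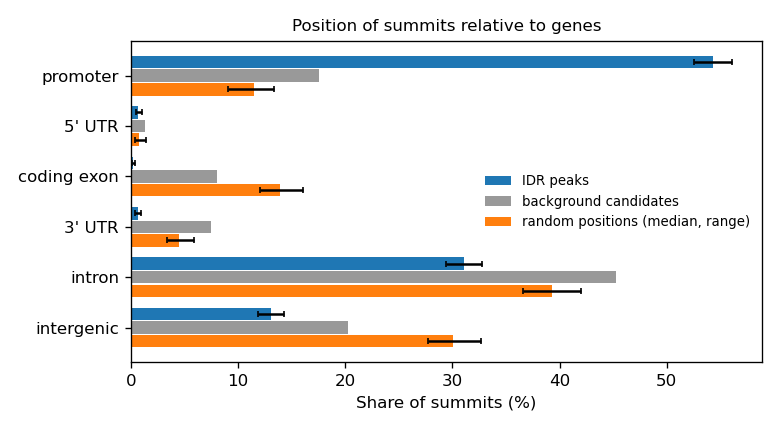
Share of summits (x axis, %) in each of 6 gene parts (y axis) for IDR peaks with exact 95% intervals, for background candidates, and for 1000 random relocations (median, with bars for the range). Promoters held 54.3% of IDR summits, 17.6% of background candidates and a median of 11.5% of random positions.

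Promoter summits lay just upstream of the start site. Of the 1687, 1394 (82.6%, 95% interval 80.7 to 84.4) lay upstream of the nearest TSS in the direction of transcription. The median offset was -87 bp, with quartiles of -168 and -23 bp. Of the 1687, 684 lay at genes with a divergent partner within 500 bp, where a summit between both TSSs is upstream of either. The upstream share was not computed for the other promoters or for background candidates.

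Chromosome 4, a small autosome, carried fewer IDR peaks than its length predicts. It held 14 peaks against 31.3 for its share of the length (ratio 0.448, 95% interval 0.245 to 0.750, exact two-sided binomial test, p = 0.000827, adjusted exact p = 0.00496). Its 749 pooled candidates put 1.87% into the IDR set, against 9.77% to 11.5% on the other arms. Chromosome 4 is also poorer in genes for its length, with 80 protein-coding genes on 1348131 bp, against 2196 on 23542271 bp of X. Counts were not compared with each arm's share of genes, so the low count cannot be told apart from low gene density. Arm 2L held 594 peaks (ratio 1.09, p = 0.0236, adjusted exact p = 0.0707) and X held 514 (ratio 0.941, p = 0.132, adjusted exact p = 0.263). Arms 2R, 3L and 3R had ratios of 0.985, 1.02 and 0.994 with adjusted exact p of 0.857, 0.806 and 0.883. The 6 arms were adjusted together. Arm 2L passed the threshold with the 1553 strongest peaks (ratio 1.14, adjusted exact p = 0.0370) and without replicate 2 (ratio 1.13, adjusted exact p = 0.00265), and X without replicate 2 (ratio 0.910, adjusted exact p = 0.0418).

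The gene lists asked which groups of genes carried promoter peaks. Of 13945 protein-coding genes, 2202 (15.8%, 95% interval 15.2 to 16.4) had an IDR summit within 500 bp of a TSS. Genes for cytosolic ribosomal proteins stood furthest above the rest, with 60 of 93 (64.5%, 95% interval 53.9 to 74.2) against 15.5% of other genes (odds ratio 9.94, Fisher's exact test, two-sided, p = 2.83e-26, adjusted exact p = 5.94e-25). The strongest members were RpL30 (signal 649.1, summit 63 bp from the TSS), RpS27 (610.2, 18 bp), RpL7 (546.6, 24 bp) and RpL23A (497.1, 92 bp). The Polycomb and Trithorax group, regulators that keep genes silent or active, had 12 of 26 (46.2%, odds ratio 4.59, p = 0.000256, adjusted exact p = 0.00135), led by ph-p (1273.3), brm (315.4), Sfmbt (196.6) and E(z) (166.4).

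Further lists above the other genes had larger p-values, each with an adjusted p of 0.0301 by Fisher's exact test. Insulator and architectural proteins had 8 of 21 (38.1%, odds ratio 3.29, exact p = 0.0113), among them Chro (1237.6), Cp190 (341.0), Dref (279.3) and Trl (204.6). Cell cycle and DNA replication genes had 12 of 38 (31.6%, odds ratio 2.47, exact p = 0.0129), among them dpa (213.0), dup (179.1), Dp (165.0) and BubR1 (155.7). Translation initiation and elongation factors had 15 of 51 (29.4%, odds ratio 2.23, exact p = 0.0119), led by eIF3b (670.7), eIF6 (626.1), eEF1gamma (405.1) and eIF4EHP (297.5). Mitochondrial ribosomal proteins had 20 of 73 (27.4%, odds ratio 2.02, exact p = 0.00971), led by mRpS10 (1116.2), mRpS23 (981.3), mRpL41 (938.4) and mRpL23 (777.9). The mRpS10 peak is the one nearest to Art3, and the mRpS23 peak the one nearest to CenG1A. The Dref peak is also the RpL13 peak, 38 bp from the TSS of Dref and 46 bp from that of RpL13.

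Of the lists of genes used in differentiated tissues, 3 carried no promoter peak. None of 179 chemoreceptor genes had one, which allows a share of up to 1.68% by the rule of 3 counts (exact 95% interval to 2.04%, p = 6.69e-14, adjusted exact p = 7.03e-13). Without replicate 2, 1 of the 179 had one (0.559%, 95% interval 0.0141 to 3.07, adjusted exact p = 6.95e-11), and the odds ratio was 0.0306 against 0.0146. None of 120 cuticle protein genes had one (up to 2.5%, exact 95% interval to 3.03%, p = 1.49e-09, adjusted exact p = 1.04e-08). None of 46 genes for gut proteases, amylases, maltases, larval serum proteins and yolk proteins had one (up to 6.52%, exact 95% interval to 7.71%, p = 0.000753, adjusted exact p = 0.00316). Members of these lists often lie in clusters.

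The developmental regulators were among the lists that did not pass the test. No Hox gene of 8 had a promoter peak, which allows up to 37.5% (exact 95% interval to 36.9%, adjusted exact p = 0.652). Segmentation genes had 2 of 31 (6.45%, adjusted exact p = 0.349), bcd (168.6) and cnc (156.6); the odds ratio of 0.367 was 0.591 without replicate 2 (3 of 31). Dorsoventral and mesoderm regulators had 3 of 33 (9.09%, adjusted exact p = 0.520), Egfr (392.6), tin (154.6) and htl (124.8); the odds ratio of 0.533 was 0.987 without replicate 2 (5 of 33). Neural markers had 3 of 36 (8.33%, adjusted exact p = 0.429), elav (459.6), Fas2 (106.6) and insc (97.1); the odds ratio of 0.484 was 0.145 without replicate 3 (1 of 36, adjusted exact p = 0.0588). Muscle genes, a list not limited to structural proteins, had 4 of 30 (13.3%, adjusted exact p = 1), Tm1 (874.3), Msp300 (267.4), mbc (226.4) and sls (213.2).

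Germline genes had 7 of 28 (25%, adjusted exact p = 0.336), led by bgcn (243.9), orb (239.4), Sxl (139.2) and stau (134.0). Heat shock proteins had 6 of 24 (25%, adjusted exact p = 0.357), led by Hsp27 (505.6), Hsp83 (447.1), Hsc70-5 (202.3) and Hsp26 (160.3). The preset list for ZAD zinc finger proteins, the family of CG4854, had 12 of 49 (24.5%, adjusted exact p = 0.238). It was led by CG1792 (642.6), CG10147 (448.1), CG4820 (251.4) and Phs (223.1). Its members were listed by name, without a check for the ZAD domain, and do not stand for the whole family. The CG4820 peak is also the RpS25 peak, 194 bp from the TSS of CG4820 and 54 bp from that of RpS25. The ZAD genes idc and trem shared 1 peak, as did CG14711 and Zaf1. Dosage compensation genes had 2 of 8 (25%, adjusted exact p = 0.429), JIL-1 (142.2) and Sxl (139.2); the odds ratio of 1.78 was 3.32 without replicate 2 (3 of 8, adjusted exact p = 0.232). Aminoacyl tRNA synthetases had 8 of 35 (22.9%, adjusted exact p = 0.357), led by SerRS (288.5), GluProRS (228.7), ThrRS (204.7) and beta-PheRS (203.1). Oxidative phosphorylation genes had 19 of 89 (21.3%, adjusted exact p = 0.279), led by COX5A (587.5), ND-ASHI (381.5), Cyt-c-d (355.9) and ND-75 (280.1). Proteasome subunits had 10 of 48 (20.8%, adjusted exact p = 0.424), led by Rpn5 (235.2), Rpn3 (176.8), Rpt5 (168.0) and Rpn6 (142.7).

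Cytosolic ribosomal proteins and cuticle proteins passed the threshold in all 8 alternatives. The Polycomb and Trithorax group did so in 5, insulator proteins in 3, and cell cycle genes, translation factors and mitochondrial ribosomal proteins in 2 each, so these calls depend on the peak set, the replicate and the window. For the Polycomb and Trithorax group the odds ratio was 2.93 without replicate 2 (adjusted exact p = 0.0423) and 2.69 without replicate 3 (adjusted exact p = 0.0659). Without replicate 2, cell cycle genes missed the threshold (odds ratio 1.72, adjusted exact p = 0.301). So did translation factors (odds ratio 2.10 against 2.23, adjusted exact p = 0.0875) and mitochondrial ribosomal proteins (1.815 against 2.02, adjusted exact p = 0.0877). Without replicate 3, translation factors (2.12, adjusted exact p = 0.0588) and insulator proteins (2.54 against 3.29, adjusted exact p = 0.143) missed it. Among genes with a candidate entry, chemoreceptors (adjusted exact p = 0.0526) and the gut, serum and yolk protein genes (adjusted exact p = 1) did not pass, nor did the latter with the 1553 strongest peaks (adjusted exact p = 0.108). When each peak was assigned to the nearest TSS at any distance, dorsoventral and mesoderm regulators stood above other genes (odds ratio 5.35, adjusted exact p = 2.29e-05), as did segmentation genes (2.76, adjusted exact p = 0.0323).

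**Figure D3:**
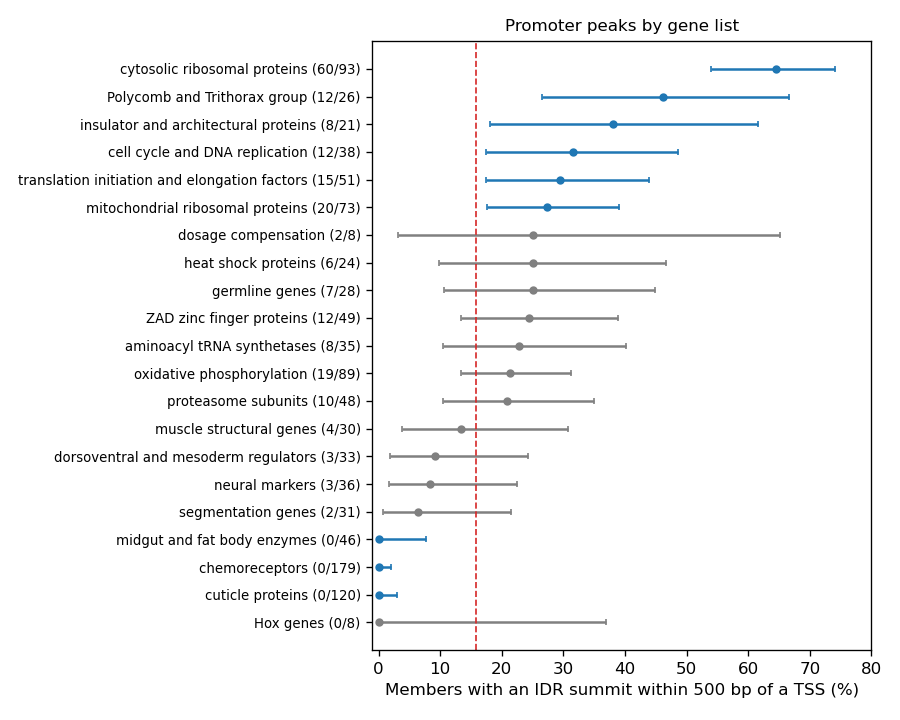
Share of each list's members with an IDR summit within 500 bp of a TSS (x axis, %), with exact 95% intervals; the y axis names the list with its counts. Blue marks the lists with an adjusted p under the threshold, grey the others, and the dashed line the 15.8% of all protein-coding genes.

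The next comparison asked which known sequence elements lay under the summits. The DRE, the site of the replication-related factor DREF, occurred at 82 of 3106 summits (2.64%, 95% interval 2.11 to 3.27), against 0.496% of background windows (odds ratio 5.44, Fisher's exact test, two-sided, p = 4.46e-23, adjusted exact p = 7.14e-22). Windows 500 bp away held it in 0.258% (exact McNemar test, two-sided, adjusted exact p = 1.11e-15). The core CGATA of the insulator protein BEAF-32 occurred at 18.1% against 11.8% (odds ratio 1.65, adjusted exact p = 1.30e-18) and 11.9% in the flanks. The DRE contains this core, so the 2 results are not independent. The M1BP site occurred at 1.03% against 0.237% (odds ratio 4.39, adjusted exact p = 8.75e-08). The TATA box sequence occurred at 18.8% against 16.2% (odds ratio 1.2, adjusted exact p = 0.00195), and the CTCF core at 4.67% against 3.19% (odds ratio 1.49, adjusted exact p = 0.000416).

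The E-box CAGCTG stood close to the threshold (4.89% against 3.96%, odds ratio 1.25, adjusted exact p = 0.0484). It missed it without replicate 2 (adjusted exact p = 0.0557) and without replicate 3 (0.0965). It also missed it with 25 bp windows (odds ratio 1.23, adjusted exact p = 0.274) and with the 1553 strongest peaks (odds ratio 0.991). CTCF core and this E-box were not above the flanking windows, which held 4.31% and 5.06% (exact McNemar test, adjusted exact p = 0.643 and 0.813). The CA repeat was rarer at summits (0.386% against 0.886%, odds ratio 0.434, adjusted exact p = 0.00857). It missed the threshold with 25 bp windows (adjusted exact p = 0.0616), 100 bp windows (0.184) and matched background (0.258). Without replicate 2 the CA repeat (adjusted exact p = 0.0634) and the TATA box (adjusted exact p = 0.0562) missed the threshold, and M1BP had an odds ratio of 2.9. The other 9 of 16 motifs did not pass the test against background: GAGA, the Clamp GA repeat, Zelda, the Su(Hw) core, the initiator, the homeodomain site, Ohler motif 6, and the E-boxes CACGTG and CATATG (adjusted exact p from 0.0629 to 0.911). With 100 bp windows, Ohler motif 6 (odds ratio 3.24, adjusted exact p = 2.30e-05) and GAGA (odds ratio 1.36, against 0.889 with 50 bp windows, adjusted exact p = 0.0126) stood above background. Mean GC was 35.9% (SD 9.0 over 3106 windows) at summits, 39.7% in background windows and 43.9% in flanking windows. With 2914 background windows matched on GC and promoter position, DRE, the BEAF-32 core, the CTCF core and CAGCTG remained above background (adjusted exact p = 0.000111 for CAGCTG), while M1BP (odds ratio 1.69, adjusted exact p = 0.207) and the TATA box (0.865, adjusted exact p = 0.104) did not.

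A search with no preset motif returned the DRE and sequences that overlap it, and others that do not. In the odd-ranked peaks 65 of 32896 8-mers passed, and 50 of them passed again in the even-ranked peaks (one-sided Fisher's exact test). The 10 with the smallest p in the odd-ranked peaks all passed in the even-ranked ones, with adjusted exact p from 2.01e-14 to 0.00953. With the roles of odd- and even-ranked peaks exchanged, 43 passed at first and 38 of them again, and 5 of the 10 leading 8-mers were the same. The shares that follow are from the even-ranked peaks, which did not choose the 8-mers. Those that contain ATCG were ATCGATAG (3.22% of IDR summits against 0.565% of background), TATCGATA (2.70% against 0.443%), ACTATCGA (2.19% against 0.336%), AACTATCG (1.87% against 0.244%), AATCGATA (1.42% against 0.733%) and GCTATCGA (1.22% against 0.290%). Each of these holds the core CGATA on 1 strand, so they are not separate signals. Those without ATCG were CAACACTG (2.19% against 0.351%), CGTTGCCA (1.61% against 0.504%), GCGTTGCC (1.54% against 0.397%) and AGTGTTGG (1.22% against 0.443%). CAACACTG had the smallest p of all in the odd-ranked peaks. It shares CAACACT with the reverse complement of AGTGTTGG, and CGTTGCCA and GCGTTGCC share CGTTGCC, so the members of each pair are not separate signals either. At least 1 of the 10 occurred at 148 of 1553 even-ranked summits (9.53%), against 2.95% of background windows. At promoter summits among these the share was 15.2% (95% interval 12.8 to 17.8), and away from promoters 3.15% (95% interval 2.01 to 4.70). With a background matched on GC, which holds fewer windows, 10 8-mers passed in the odd-ranked peaks and 9 of these in the even-ranked ones. Of the 10 leading 8-mers, 7 were the same.

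**Figure D4:**
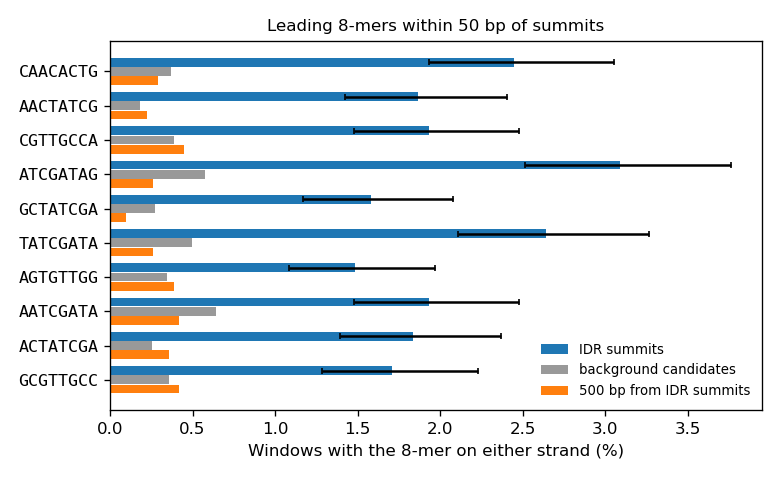
Share of windows that hold each of the 10 leading 8-mers on either strand (x axis, %; y axis, 8-mer), at IDR summits with exact 95% intervals, at background candidates and 500 bp from IDR summits. All 3106 peaks are shown, including the odd-ranked ones that chose the 8-mers; ATCGATAG reached 3.09% at IDR summits, against 0.573% in background windows.

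Stronger peaks lay at promoters more often. The share at promoters was 60.3% (95% interval 56.3 to 64.2) in the strongest of 5 classes by signal and 53.0% (49.0 to 57.0) in the weakest (trend permutation test, two-sided, p = 0.00228). This difference of 7.31 percentage points was 16.8 without replicate 3, 6.35 without replicate 2 and 13.3 with 10 classes by signal. For the DRE no trend was detected, with 1.61% in the strongest class and 2.90% in the weakest (permutation p = 0.286), although without replicate 3 its share was lower in the strongest class (permutation p = 0.0132).

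The same libraries gave 3716 IDR peaks on dm3 and 3106 on dm6. The candidate lists held 30000 entries on each build, and the median width of IDR peaks was 404 bp on dm3 and 358 bp on dm6. The signal at the last IDR peak was 83.9 on dm3 and 95.2 on dm6. The arms took nearly the same shares on both builds, with 3R at 23.7% on dm3 and 23.8% on dm6, 3L at 21.3% and 21.4%, and X at 17.0% and 16.6%. Arm 2L took 19.0% and 19.1%, 2R 18.4% and 18.6%, and chromosome 4 0.511% and 0.451%.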

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

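The alternative with 1 TSS per gene was chosen after seeing the data. No paired analysis was possible because the samples form 1 group. The dm3 alternative for arms was not run, since no dm3 arm lengths were at hand. Read depth is unknown, so what it limits was not assessed. Of 332 alternative values, 246 kept their direction and their side of the threshold or stayed close. Replicate overlap ranged from 49.9% to 69.0% and the promoter share from 42.1% to 63.4%, and Spearman's rho was 0.593 on dm3. For what follows the cause was not tested.

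Lists above other genes fell from 6 to 2 with a 1000 bp window, to 1 with the 1553 strongest peaks and to 1 among genes with a candidate entry, where 1 list instead of 3 was below; fewer peaks or genes enter the last 2. Leaving out a replicate gave 3 such lists in either case. Motifs below background went from 1 to 0 with 25 bp windows, 100 bp windows and matched background, and ranged from 0 to 1 without a replicate. The GC-matched background gave 9 8-mers that passed in both sets of peaks, against 50, and 7 of the 10 leading 8-mers were the same. Matching also leaves fewer background windows, so the fall cannot be put down to base composition alone.

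Arm 2L had a ratio of 1.14 with the 1553 strongest peaks. Without a replicate, 2L ranged from 1.07 to 1.13, 2R from 0.944 to 1.00, 3R from 0.993 to 1.02 and X from 0.910 to 0.965. The DRE share in the strongest class minus the weakest was -2.10 percentage points without replicate 2, -1.93 without replicate 3 and -0.972 with 10 classes by signal, against -1.29.

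Odds ratios that changed sides with the nearest TSS at any distance were 0.529 for mitochondrial ribosomal proteins, 0.853 for proteasome subunits, 0.976 for ZAD proteins, 1.67 for Hox genes, 2.76 for segmentation genes, 5.35 for dorsoventral and mesoderm regulators and 1.82 for muscle genes. With the 1553 strongest peaks they were 0.691 for proteasome subunits, 1.60 for muscle genes, 0.798 for germline genes, 0.610 for dosage compensation, 0.757 for Zelda and 0.991 for the E-box CAGCTG. Among genes with a candidate entry they were 0.922 for oxidative phosphorylation and 0.936 for ZAD proteins. A 200 bp window gave 0.898 for germline genes, and 1 TSS per gene 0.875 for dosage compensation.

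For motifs, 25 bp windows gave 0.960 for the homeodomain site, and 100 bp windows 1.36 for GAGA, 1.05 for the E-box CACGTG, 1.24 for the Clamp repeat and 0.957 for the homeodomain site. Matched background gave 1.0 for Ohler motif 6, 0.865 for the TATA box and 0.870 for the homeodomain site. Without replicate 2 the values were 1.29 for GAGA, 0.912 for Zelda, 1.58 for the Clamp repeat and 0.960 for the homeodomain site, and without replicate 3 they were 1.06 for the E-box CACGTG and 1.02 for the Clamp repeat, while the homeodomain site stayed on its side at 1.12.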

Other observations

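The tests of ribosomal protein peaks, of small nuclear, small nucleolar and other non-coding RNA genes, of summits away from promoters and of summits at divergent promoters were chosen after the results were seen. Promoter peaks of cytosolic ribosomal protein genes differed in sequence and strength from other promoter peaks. Of 63 such peaks, 50.8% held the BEAF-32 core within 50 bp of the summit, against 23.5% of 1624 other promoter peaks (Fisher's exact test, two-sided, adjusted p = 0.000107 over 26 tests). AACTATCG occurred at 15.9% against 2.71% (adjusted exact p = 0.000218) and ATCGATAG at 17.5% against 4.99% (adjusted exact p = 0.00352). The DRE occurred at 14.3% against 4.25% (adjusted exact p = 0.00976). All of these hold the core CGATA on 1 strand, so they are not separate signals. The M1BP site, which lacks this core, occurred at 7.94% against 1.60% (adjusted exact p = 0.0215). The TATA box was rarer, at 6.35% against 17.9% (adjusted exact p = 0.0482). Their median signal was 210.5 against 149.0, above 99.99% of 10000 random draws of as many promoter peaks.

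Small nuclear RNA genes lay near IDR summits more often than near random positions, with 6 summits within 500 bp of a start (0.193%, against a random median of 0.0322% and 0.0153% of background candidates, two-sided permutation p over relocated positions = 0.002, adjusted p = 0.00267). For small nucleolar RNA genes the share was 0.354%, above a random median of 0.129% (permutation adjusted p = 0.00267) and close to the 0.328% of background candidates. Summits within 500 bp of other non-coding RNA starts made up 4.41%, against a random median of 2.00% and 2.69% of background candidates.

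Developmental regulators had peaks away from promoters, and no excess over background candidates was detected. Of 1419 IDR summits away from promoters, 26 (1.83%) had a dorsoventral or mesoderm regulator as the nearest gene, against 1.37% of 10792 background summits (odds ratio 1.34, 95% interval 0.881 to 2.04, Fisher's exact test, two-sided, p = 0.188, adjusted exact p = 0.791 over 21 lists). They included 5 near ush, 4 near pnt and 3 near Mef2, named after their values were seen. For segmentation genes the shares were 1.06% and 0.936% (adjusted exact p = 1).

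For 3 patterns, technical explanations were weighed; the tests of ubiquitously used promoters with and without paralogues, of flanking windows, of windows elsewhere in the promoter and of dm3 scaffolds were chosen after the result was seen. No biological explanation of these 3 patterns was tested, and the design has 1 group. The share of ribosomal protein promoters with a peak was 64.5%. If it reflected signal common to promoters used in every cell, proteasome, oxidative phosphorylation and mitochondrial ribosomal protein genes would share it, but 23.3% of these 210 genes had a peak (odds ratio between them 5.97, 95% interval 3.51 to 10.2). Of these genes, 38 are named as paralogues of other members and none of the 38 had a peak; without them the share was 28.5% of 172 (95% interval 21.9 to 35.9, odds ratio 4.56, 95% interval 2.66 to 7.82). Both shares lay above the 15.8% of all protein-coding genes, so these tests do not exclude a signal that such promoters share in part. Members named as paralogues were left out of the comparison lists only. The cytosolic ribosomal protein list kept such members: RpL7-like, RpL22-like, RpL24-like and RpS28-like without a peak and RpLP0-like with a peak. How widely each gene is expressed was not analysed here. The odds ratio stayed at 8.40 (95% interval 5.12 to 13.8) over 40 strata of divergent partner, number of TSSs and promoter GC, and at 6.10 (3.73 to 9.97) among genes with a candidate entry. Ribosomal protein promoters are also among the most heavily transcribed, and recovery of such chromatin without binding of CG4854 may contribute; mock immunoprecipitations were not analysed here, so this stays open.

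The DRE at summits was not removed by matching background windows on GC and promoter position (odds ratio 2.37, 95% interval 1.57 to 3.57, against 5.44 unmatched), so these account for part of the difference at most. Of windows 500 bp from the summits, 0.258% held it, against 2.64% at summits, though many of these windows lie outside promoters. At promoter summits alone the share was 4.62% of 1687 (95% interval 3.67 to 5.74), against 1.36% (0.866 to 2.04) in 1 window drawn elsewhere within 500 bp of the same TSS (exact McNemar test, two-sided, p = 1.16e-08). Occurrence spread evenly over the promoter does not account for the difference. Whether CG4854 contacts the sequence or lies at promoters that DREF or BEAF-32 occupy cannot be decided from these lists.

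The 610 additional IDR peaks on dm3 did not lie on scaffolds that dm3 alone has, where 0 of the dm3 IDR peaks were found. At the rank of the last dm6 peak the signal on dm3 differed by -1.01%. This lay just outside the bound set for unchanged signals, so the test was undecided. A cut at the same pooled signal would give fewer peaks on dm3, not more. Replicate signals, from which the IDR set also derives, were not compared at matched ranks between builds, so changed signals stay open. The dm3 set reached down to a signal of 83.9, against 95.2 on dm6. What placed this deeper cut cannot be told, because the IDR values per peak were not analysed here.

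A hypothesis that divergent promoters carry peaks more often was tested. Of 3815 genes with a divergent partner within 500 bp, 1214 (31.8%) had a peak, against 9.75% of 10130 others (odds ratio 4.32, 95% interval 3.93 to 4.75, Fisher's exact test, two-sided, p = 2.54e-201). As 1 summit can count for both partners, summits were also compared: 40.5% of IDR promoter summits lay at such genes, against 21.6% of background promoter summits (odds ratio 2.48, 95% interval 2.16 to 2.85). A second hypothesis, of peaks at tRNA genes, was left undecided: 8 summits (0.258%) lay within 500 bp of a tRNA start, against a random median of 0.161% and 0.466% of background candidates (two-sided permutation p over relocated positions = 0.270).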
